A study of Mus musculus with 24 samples.

How the data were processed

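Polyadenylated RNA was sequenced as TruSeq libraries on a HiSeq2000 from wild-type (WT) and AGO2 knockout (KO) E14 mouse embryonic stem cells (mESCs), undifferentiated or during directed differentiation towards extraembryonic endoderm (XEN). The series lists 24 samples in 12 groups of 2, and group and day were taken from the sample labels. The diff_XEN counts were matched to their groups by the column names of the series table, which also name the KO clones. The counts of 22 libraries were used, namely 16 libraries of days 1 to 4 and 6 endpoint libraries, which were WT mESC, WT diff_XEN and KO diff_XEN. Per the labels, the day 1 to 4 libraries were sequenced in the same run, whereas the mESC and diff_XEN libraries were re-used from earlier studies. The 2 KO mESC samples were not analysed here, because 3 columns of the series table carry names that no label ties to them. Those 3 columns were used in no step. Of 13 comparisons planned, 10 were made and the 3 that need the KO mESC group were not. Replicates were not stated to be separate cultures, so p-values measure only the spread between these samples, which may be technical.

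The deposited values were raw read counts per gene, whole numbers whose totals differed between libraries. Per the submitters' processing notes, STAR 2.5.0c and featureCounts 1.4.5-p1 were used with the mm10 build, and the annotation release and the strand setting of the counting were not given in the sources used here. Reads of overlapping or antisense genes and of near-identical gene copies can therefore be split or shared. Some such genes are named as uncertain, but the lack of that mark does not show that a gene was counted uniquely. The day 1 to 4 files listed 30590 gene symbols and the endpoint files 43629 Ensembl identifiers, of which 42462 were matched to a symbol. Coordinates were taken from a GRCm38 annotation, the assembly of mm10. No genome sequence was used. Total counts per library ranged from 10601574 to 27147835 in the course and from 13941826 to 40139219 in the endpoint libraries. Replicates of every group differed by more than sampling noise, with a chi-square per degree of freedom of 12.6 to 149 over genes with at least 20 counts, and none was merged.

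Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, the default expression filter by group, robust estimation and a group means model without covariates. The 16 course libraries formed 1 fit of 8 groups. KO and WT diff_XEN were compared in a fit of the 4 libraries of the series table. WT diff_XEN and WT mESC were compared in a fit of all 6 endpoint libraries. For that last fit the plan asked for a single table, but the mESC counts were in files of their own with the same identifiers in the same order, so the tables were joined. That step departs from the plan and was chosen after the files were seen. The endpoint libraries and the course were not put in the same fit, and no level is compared across them. Genes were called at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested. Fold changes are log2 values with the standard error derived from the quasi-likelihood F statistic, and levels are CPM, that is counts relative to the TMM-scaled library size, as mean ± SD of 2 libraries where not stated otherwise.

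Gene names followed a fixed rule. Ago2 came first, and 10 lineage genes were always given. Up to 8 genes with the largest rise and 8 with the largest fall were added per comparison among called genes with a mean of at least 5 CPM and no overlap between the groups, together with the members of each list with the smallest p. Predicted and clone-named genes were counted but not named, and some genes that the rule takes are not reported here. A total of 28 gene lists was tested with camera in limma 3.58.1 at a preset correlation of 0.01, and again with the correlation estimated from the data and with fry. Camera compares a list with all other genes, and its adjusted p is taken over the lists of a comparison. Members of a list are counted as risen or fallen over all genes tested, and a second count is adjusted over the list alone. Groups, comparisons, tests, lists, the naming rule and the alternatives were fixed before the data were examined, except where stated.

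A fold against a group with no counts is given as a lower bound against a floor of 3 counts over the group. Against 1 to 3 counts, the ratio is given with its exact 95% counting interval. Such floors and intervals cover counting error only. The alternatives were DESeq2 size factors, DESeq2 1.42.0 with its Wald test, no expression filter, an additional 2-fold threshold, the replicate number as a block, a fit of the 4 compared libraries alone and leaving out each library in turn. Where that leaves a group with 1 library, the lone library is assumed to vary like the other groups. The pipeline was tested on simulated counts with 200 changed genes. These were drawn only from well-counted genes, so recovery for genes with few counts was not tried. It recovered 58% of 2-fold and 94% of 4-fold changes for KO versus WT at day 4, among 17448 genes. For KO versus WT in diff_XEN it recovered 10% and 79% among 16323 genes, and for the difference between genotypes in the change from day 1 to day 4 it recovered 15% and 80% among 17448 genes. The adjusted p limit depends on how many genes change, so these shares do not carry over to real comparisons with many more calls.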

Results

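The series followed E14 mESCs, a mouse embryonic stem cell line, under a protocol directed towards XEN cells, the cultured counterpart of the endoderm that lines the yolk sac. Cells were grown with 15% serum, 0.1 µM retinoic acid and 10 ng/mL activin A in a protocol of 5 days. WT cells and cells lacking AGO2, the Argonaute protein that binds small RNAs and can cleave their targets, were sampled on days 1, 2, 3 and 4, with 2 libraries per day and genotype. The set was completed by 2 diff_XEN libraries of each genotype and by WT mESC libraries at passages 33 and 42. Total counts per library ranged from 10601574 to 27147835 on days 1 to 4, and among the endpoint libraries from 13941826 for KO clone C4 to 40139219 for a WT mESC library. The comparisons ask how the transcriptome moves along the protocol, and how it differs when Ago2 is disrupted. By their column names, KO libraries of diff_XEN came from clones C4 and 5-3, 1 library each. The clone behind the day 1 to 4 KO libraries was not stated.

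Ago2, on chromosome 15 from 73095844 to 73184935 on the minus strand (mm10), was lower in every KO library than in every WT library of the same day. At day 1 it stood at 332 and 414 CPM in WT and at 43.4 and 33.8 CPM in KO. WT libraries held 272 and 201 CPM at day 2, 307 and 186 CPM at day 3, and 514 and 581 CPM at day 4. KO libraries held 56.1 and 84.6 CPM at day 2, 77.4 and 122 CPM at day 3, and 109 and 148 CPM at day 4. The log2 fold change was -3.27 ± 0.31 (SE, adjusted p = 3.18e-04) at day 1, -1.75 ± 0.30 (adjusted p = 0.00893) at day 2, -1.31 ± 0.29 (adjusted p = 0.0219) at day 3 and -2.09 ± 0.30 (adjusted p = 6.08e-04) at day 4. The day 2 call was lost without WT replicate 1 (-1.51) or KO replicate 1 (-1.48), and the day 3 call without WT replicate 1 (-0.90) or KO replicate 1 (-0.997). Between day 1 and day 4 Ago2 rose within the KO course by 1.74 ± 0.30 on the log2 scale (adjusted p = 1.85e-04). The difference of this change from that in WT did not pass the test (1.18 ± 0.41, adjusted p = 0.0899). Among the endpoint libraries, WT diff_XEN held 389 and 427 CPM, KO clone C4 115 CPM, KO clone 5-3 9.35 CPM, and WT mESC 619 and 311 CPM. KO versus WT in diff_XEN was -2.72 ± 1.04, which did not pass the test (adjusted p = 0.0808). Without clone C4 it passed (-5.37), and without clone 5-3 as well (-1.82). Counts over the whole gene do not show which part of the transcript remained.

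**Figure D1:**
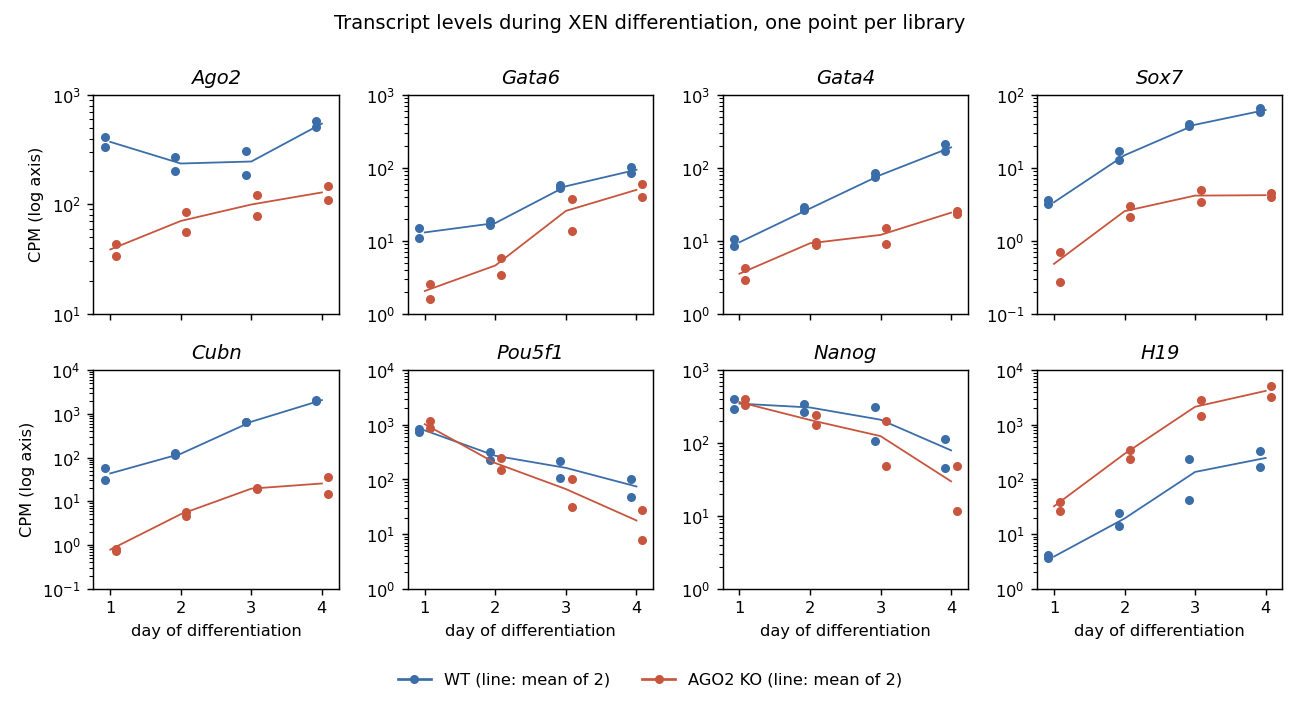
Transcript levels in CPM on log axes against the day of differentiation, with 1 point per library and lines through the mean of 2 libraries for WT and AGO2 KO. Cubn reached 2074 ± 89.4 CPM in WT and 25.6 ± 14.9 CPM in KO at day 4, whereas H19 was at 247 ± 114 CPM in WT and 4185 ± 1311 CPM in KO.

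From day 1 to day 4 of the WT course the endoderm regulators rose and the pluripotency factors fell. Gata4 rose by 4.33 ± 0.24 on the log2 scale (SE, n = 2 libraries per day), Gata6 by 2.86 ± 0.42, Sox17 by 4.60 ± 0.44, Sox7 by 4.21 ± 0.29, Pdgfra, a receptor of primitive endoderm, by 3.44 ± 0.38 and Dab2, an endocytic adaptor, by 4.67 ± 0.25. Pou5f1 fell by 3.41 ± 0.67, Sox2 by 2.73 ± 0.63, Esrrb by 2.76 ± 0.69 and Nanog by 2.13 ± 0.75. Among the largest rises, Ccdc80 was at least 1214-fold higher at day 4, Pcdh7 at least 581-fold, Dkk2 at least 289-fold, Dcn, which encodes decorin, at least 246-fold and Serpina3g at least 186-fold. Col3a1 was higher with a count ratio of 7065 (95% interval 1955 to 58351), and Tnc and Col12a1 rose by 11.22 ± 0.95 and 10.75 ± 1.20. The largest falls were those of Foxn4 (-5.52 ± 0.51), Inhbb (-5.21 ± 0.64), Nphs1 (-5.20 ± 0.91), Dmrt1 (-5.12 ± 0.68), Kirrel2 (-5.09 ± 0.58), Rasgrp2 (-5.06 ± 0.38), Stmn3 (-4.87 ± 0.46) and Myo1f (-4.75 ± 0.51). In all, 8588 of 17694 genes were called, 4760 higher and 3828 lower at day 4. The Nanog call was lost without WT day 1 replicate 1 (-1.92), day 1 replicate 2 (-2.36) or day 4 replicate 1 (-1.64), and those of Esrrb and Sox2 without day 4 replicate 1 (-2.39 and -2.49).

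All 20 measured members of the primitive endoderm and XEN list rose in WT (20 adjusted over the list alone, median 4.34), among them the laminin gene Lamb1 (3.25 ± 0.16). The camera test gave adjusted p = 3.76e-14, and adjusted p = 0.0926 with an estimated correlation. Of 15 parietal endoderm genes 14 rose (14 adjusted over the list alone, median 4.75), with the basement membrane collagen gene Col4a2 at 4.78 ± 0.27. This list had adjusted p = 4.99e-10, and adjusted p = 0.206 with an estimated correlation. Of 15 visceral endoderm genes 13 rose (13 rose and 1 fell adjusted over the list alone, median 3.94), including Cubn (5.58 ± 0.38) and Amn (4.17 ± 0.32), the subunits of the cubam receptor. Its adjusted p was 1.62e-04, and adjusted p = 0.274 with an estimated correlation. The fibroblast and mesenchyme list had 16 of 17 members higher and 1 lower (the same counts adjusted over the list alone, adjusted p = 1.45e-08, adjusted p = 0.239 with an estimated correlation). Its median was 4.93, or 4.31 with members lacking counts at their bound. Of 16 naive pluripotency genes 10 fell and 2 rose, with the same counts adjusted over the list alone (median -1.90, adjusted p = 0.00641, adjusted p = 0.618 with an estimated correlation), among them Fgf4 (-3.48 ± 0.56). Of 12 general pluripotency genes 10 fell, and 10 adjusted over the list alone (median -1.70, adjusted p = 5.60e-04, adjusted p = 0.408 with an estimated correlation). The imprinted list had 19 of 25 members higher and 2 lower (20 and 2 adjusted over the list alone, median 2.23), led by the growth factor gene Igf2 (6.57 ± 0.32). Its adjusted p was 3.36e-06, and adjusted p = 0.206 with an estimated correlation. Cell cycle genes fell in 12 of 16 cases (13 adjusted over the list alone, median -0.48, adjusted p = 1.86e-04, adjusted p = 0.274 with an estimated correlation), including Pcna (-1.19 ± 0.13).

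In the KO course the 6 endoderm regulators and markers given for WT also rose from day 1 to day 4 and the 4 pluripotency factors fell, whereas visceral endoderm genes went both ways. Gata6 rose by 4.60 ± 0.48 on the log2 scale, Sox17 by 5.07 ± 0.54, Pdgfra by 4.06 ± 0.41, Dab2 by 4.28 ± 0.25, Sox7 by 3.16 ± 0.36 and Gata4 by 2.78 ± 0.24. Pou5f1 fell by 5.84 ± 0.76, Esrrb by 3.88 ± 0.73, Nanog by 3.61 ± 0.80 and Sox2 by 3.14 ± 0.64. Col3a1 was at least 5621-fold higher at day 4, Dkk2 at least 749-fold and Serpina3g at least 178-fold. Count ratios were 14324 for Tnc (95% interval 3965 to 118283), 4999 for Ccdc80 (897 to 197495) and 2385 for Pcdh7 (428 to 94281), and Col12a1 rose by 10.55 ± 1.18. Airn, with a ratio of 1750 (314 to 69196), overlaps Igf2r on the opposite strand and is uncertain. Gjb1, a connexin gene, was lower at day 4 by a ratio of 1136 (204 to 44904). The other large falls were those of Myh13 (-7.15 ± 0.41), Gtsf1l (-7.08 ± 0.83), Platr10 (-6.94 ± 0.66), Mylpf (-6.38 ± 0.42), Slc28a1 (-6.28 ± 0.51), Stmn3 (-6.28 ± 0.46) and Foxn4 (-6.23 ± 0.53). Of the primitive endoderm and XEN list 19 of 20 members rose (19 adjusted over the list alone, median 3.78, adjusted p = 6.73e-08, adjusted p = 0.344 with an estimated correlation). Of the parietal endoderm list 14 of 15 rose and 1 fell, the same adjusted over the list alone (median 4.26, adjusted p = 1.43e-06, adjusted p = 0.344 with an estimated correlation). Of the visceral endoderm list 4 of 15 rose, among them Cubn (5.03 ± 0.44), and 3 fell, among them Hnf4a (-3.26 ± 0.39), with the same counts adjusted over the list alone. That list was not called (median 0.46, adjusted p = 0.816), and DESeq2 had 5 members higher and 3 lower. Of the naive pluripotency list 14 of 16 members fell and 1 rose, the same adjusted over the list alone (median -3.79, adjusted p = 2.83e-04, adjusted p = 0.554 with an estimated correlation). Of the general pluripotency list 11 of 12 fell, also 11 adjusted over the list alone (median -3.90, adjusted p = 2.58e-05, adjusted p = 0.415 with an estimated correlation). A total of 11724 of 17694 genes was called, 5897 higher and 5827 lower. Genes higher at day 4 in both genotypes numbered 3928, where 1586 would be shared by independent lists of 4760 and 5897. Genes lower in both numbered 3254, where 1261 would be shared.

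The change from day 1 to day 4 differed between genotypes for 1136 of 17694 genes, 459 with a higher and 677 with a lower change in KO. Among the lower ones, Hnf4a, a nuclear receptor of visceral endoderm and liver, went from 9.28 ± 0.93 to 38.5 ± 12.7 CPM in WT and from 7.13 ± 2.33 to 0.727 ± 0.285 CPM in KO, a log2 difference of -5.31 ± 0.49 (adjusted p = 9.47e-05). Tdh, the threonine dehydrogenase gene of mESCs, went from 52.1 ± 8.42 to 100.03 ± 3.30 CPM in WT and from 126 ± 14.5 to 2.07 ± 1.01 CPM in KO (-6.83 ± 0.60, adjusted p = 1.62e-04). Gata4 gained less in KO (-1.55 ± 0.32, adjusted p = 0.0163), a call lost without WT day 1 replicate 1 (-1.41) or WT day 4 replicate 1 (-1.44). The differences of Gata6 (1.74 ± 0.60, adjusted p = 0.0915) and Nanog (-1.48 ± 1.03, adjusted p = 0.379) did not pass the test. DESeq2 had 1100 with a higher and 1108 with a lower change. The number of calls was 489 without WT day 1 replicate 1, 222 without WT day 1 replicate 2, 297 and 448 without WT day 4 replicates 1 and 2, 3133 without KO day 1 replicate 1, 236 without KO day 1 replicate 2 (29 with a higher and 207 with a lower change), and 337 and 441 without KO day 4 replicates 1 and 2.

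At day 1 KO cells already held less of the endoderm transcripts Cubn, Sox7, Gata6, Dab2 and Gata4, while Pou5f1, Nanog, Esrrb and Sox2 did not differ past the threshold. Cubn was lower by a log2 fold change of -5.79 ± 0.44 (adjusted p = 8.70e-05), Sox7 by -2.83 ± 0.36 (adjusted p = 0.00109), Gata6 by -2.66 ± 0.46 (adjusted p = 0.00929), Dab2 by -2.13 ± 0.23 (adjusted p = 4.60e-04) and Gata4 by -1.42 ± 0.24 (adjusted p = 0.00627). Dkk1, a secreted WNT inhibitor, was lower by -3.65 ± 0.40 and B4galnt2 by -3.35 ± 0.46, and the collagen genes Col4a1 and Col4a2 by -2.84 ± 0.30 and -2.65 ± 0.26. Habp2 was lower in KO with a count ratio of 54.4 (95% interval 9.33 to 2188) and Tfec with 73.2 (12.7 to 2931). Aass rose in KO by 3.47 ± 0.37, Msln, encoding mesothelin, by 2.55 ± 0.25 and the neural regulator Pax6 by 2.46 ± 0.27. H19, an imprinted non-coding RNA on chromosome 7 from 142575529 to 142578143, rose by 3.05 ± 0.73. Pou5f1 (0.38 ± 0.61), Nanog (0.07 ± 0.71), Esrrb (0.25 ± 0.64) and Sox2 (0.49 ± 0.58) had adjusted p of 0.702, 0.963, 0.817 and 0.587. Of 20 primitive endoderm and XEN genes 13 fell (15 adjusted over the list alone, median -1.62, adjusted p = 6.38e-11, adjusted p = 0.189 with an estimated correlation). Of 11 genes of the 2-cell-like list, which are active in the early cleavage embryo, 7 rose (7 adjusted over the list alone, median 1.45, adjusted p = 5.83e-06, adjusted p = 0.701 with an estimated correlation). Many of these are near-identical copies and are uncertain. Of 14 cholesterol synthesis genes 4 fell (5 adjusted over the list alone, median -0.53, adjusted p = 0.0108, adjusted p = 0.918 with an estimated correlation).

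Day 1 gave 2406 called genes of 17694, 1219 higher and 1187 lower in KO, and the count moved with single libraries. It was 657 without WT replicate 1, 63 without WT replicate 2, 4225 without KO replicate 1 and 45 without KO replicate 2. Cubn, Ago2, Sox7, Dab2, Dkk1, Col4a1, Col4a2, Habp2, B4galnt2, Aass, Msln and Pax6 were called with each of these left out. The calls of Gata6 and Tfec were lost without KO replicate 2 (-2.35 and -4.98), that of Gata4 without WT replicate 2 (-1.21) or KO replicate 2 (-1.17), and that of H19 without WT replicate 1 (3.21), WT replicate 2 (2.99) or KO replicate 2 (2.77). Sox17 (-2.39 ± 0.61, adjusted p = 0.0279) lost its call without any 1 of the 4 libraries (-2.21 without WT replicate 1, -2.48 without WT replicate 2, -2.06 without KO replicate 1, -2.66 without KO replicate 2), and Pdgfra (-1.81 ± 0.40, adjusted p = 0.0195) lost it without WT replicate 2 (-1.65) or KO replicate 2 (-1.31).

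At day 2 the visceral endoderm genes Cubn (-4.59 ± 0.37, adjusted p = 6.75e-05) and Amn (-3.09 ± 0.36, adjusted p = 6.45e-04) were lower in KO, as were Sox7 (-2.54 ± 0.28), Lama1, a laminin gene of Reichert's membrane (-2.38 ± 0.30), and Gata4 (-1.58 ± 0.22). Aqp8, an aquaporin gene, was at least 32.8-fold lower, and Habp2 was lower with a count ratio of 116 (95% interval 20.3 to 4628). Klb (-3.60 ± 0.34), Srgn (-3.48 ± 0.26) and Tfec (-3.96 ± 0.49) fell too. Among higher genes were Msln (2.29 ± 0.25), Pax6 (1.83 ± 0.26), the imprinted zinc finger gene Plagl1 (5.18 ± 0.71) and the Hedgehog receptor gene Ptch1 (2.19 ± 0.30). Gata6 (-1.93 ± 0.43, adjusted p = 0.0432) and Dab2 (-1.09 ± 0.22, adjusted p = 0.0211) were called, whereas Sox17 (-1.02 ± 0.42, adjusted p = 0.275) and Pdgfra (-1.35 ± 0.36, adjusted p = 0.0855) were not. Of the primitive endoderm and XEN list 9 of 20 members fell and 1 rose (11 and 3 adjusted over the list alone, median -1.06, adjusted p = 1.89e-07, adjusted p = 0.254 with an estimated correlation). Of the visceral endoderm list 2 of 15 fell (5 adjusted over the list alone, adjusted p = 1.13e-04, adjusted p = 0.353 with an estimated correlation), with a median of -1.38, or -1.02 with members lacking counts at their bound. Day 2 had 288 calls of 17694 genes, 137 higher and 151 lower. There were 105 and 49 calls without WT replicates 1 and 2, and 96 and 50 without KO replicates 1 and 2. The Gata6 call was lost without any 1 of these (-1.83, -2.02, -1.60 and -2.37 in that order), as was that of Dab2 (-1.19, -0.98, -0.98 and -1.22). Plagl1 lost its call without WT replicate 1 (5.16) or WT replicate 2 (5.21), and Ptch1 without WT replicate 2 (2.13).

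At day 3 Gata4 (-2.76 ± 0.23, adjusted p = 1.09e-05), Sox7 (-3.27 ± 0.28, adjusted p = 1.26e-05) and Dab2 (-1.36 ± 0.22, adjusted p = 0.00303) were lower in KO. Cubn (-5.09 ± 0.37), Amn (-4.45 ± 0.35), Habp2 (-6.50 ± 0.50), Tcf23 (-6.65 ± 0.55), Pga5 (-5.75 ± 0.53), Klb (-5.55 ± 0.34) and Aqp8 (-5.08 ± 0.49) were lower as well. Plagl1 (4.71 ± 0.69), Fgf15 (3.82 ± 0.66), Sema3e (2.501 ± 0.24), Prom1 (2.43 ± 0.37) and Dmbx1 (2.69 ± 0.48) were higher. Sox17 (-1.89 ± 0.38) and Pdgfra (-2.06 ± 0.36) were called at adjusted p of 0.0127 and 0.00628, and Gata6 was not (-1.15 ± 0.40, adjusted p = 0.123), although it was called without KO replicate 2 (-2.04). Of the primitive endoderm and XEN list 11 of 20 members fell (15 fell and 1 rose adjusted over the list alone, median -1.30, adjusted p = 4.73e-13, adjusted p = 0.116 with an estimated correlation). Of the visceral endoderm list 7 of 15 fell (9 adjusted over the list alone, median -2.92, adjusted p = 2.19e-09, adjusted p = 0.163 with an estimated correlation). Of 17694 genes 854 were called, 324 higher and 530 lower. The balance of directions moved with single libraries, as there were 2643 calls without WT replicate 1 (1450 higher and 1193 lower), 271 without WT replicate 2 (52 and 219), 375 without KO replicate 1 (174 and 201) and 482 without KO replicate 2 (197 and 285), and a fit of the 4 day 3 libraries alone made 35 (2 and 33). The Sox17 call was lost without WT replicate 2 (-1.34) or KO replicate 2 (-1.65), and that of Pdgfra without WT replicate 2 (-1.63) or KO replicate 1 (-1.67).

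By day 4 the shortfall of visceral endoderm transcripts was the widest of the course in the list medians. Cubn, on chromosome 2 from 13276338 to 13491813, stood at 2074 ± 89.4 CPM in WT and 25.6 ± 14.9 CPM in KO (-6.34 ± 0.39, adjusted p = 6.33e-07), and Amn at 62.6 ± 6.06 and 0.727 ± 0.285 CPM (-6.39 ± 0.39, adjusted p = 2.52e-07). Habp2 (-6.77 ± 0.49), Tfec (-6.09 ± 0.48), Tcf23 (-6.02 ± 0.48), Nrg2 (-5.79 ± 0.40) and Hnf4a (-5.68 ± 0.39) were lower, and Gjb1 was lower with a count ratio of 63.4 (95% interval 10.9 to 2552). Gata4, on chromosome 14 from 63198922 to 63271692, was at 191 ± 25.9 CPM in WT and 24.3 ± 1.78 CPM in KO (-2.98 ± 0.23, adjusted p = 2.06e-06). Sox7 fell by 3.88 ± 0.29, Dab2 by 2.53 ± 0.23 and Sox17 by 1.92 ± 0.38 relative to WT, while Pdgfra (-1.18 ± 0.34, adjusted p = 0.0557) and Gata6 (-0.92 ± 0.39, adjusted p = 0.200) did not pass the test. Higher in KO were H19 (4.08 ± 0.72), Plagl1 (3.47 ± 0.63), the imprinted gene Nnat (2.89 ± 0.71), Msln (1.92 ± 0.25), Sema3e (1.83 ± 0.23), the neurofilament gene Ina (1.68 ± 0.27), the DNA sensor gene Aim2 (1.67 ± 0.23) and Wt1 (1.65 ± 0.27). Of the pluripotency factors given none passed the test, with Pou5f1 at -2.06 ± 0.66 (adjusted p = 0.0905), Nanog at -1.41 ± 0.75 (adjusted p = 0.328), Esrrb at -0.87 ± 0.68 (adjusted p = 0.531) and Sox2 at 0.07 ± 0.61 (adjusted p = 0.969). Of 17694 genes 1246 were called, 352 higher and 894 lower, so that 28.3% were higher. DESeq2 called 698 higher and 975 lower, or 41.7% higher. There were 605 calls without WT replicate 1, 606 without WT replicate 2, 443 without KO replicate 1 and 835 without KO replicate 2. The calls of Sox17 (-1.45) and Plagl1 (3.32) were lost without KO replicate 1, those of H19 (3.71) and Plagl1 (2.99) without WT replicate 2, and that of Nnat without any 1 of the 4 libraries (3.46 and 2.51 without WT replicates 1 and 2, 2.505 and 3.24 without KO replicates 1 and 2).

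Grouped by list, 15 of 20 primitive endoderm and XEN genes fell in KO at day 4 (18 adjusted over the list alone, median -1.94, camera adjusted p = 2.91e-18), a call that held with an estimated correlation (adjusted p = 0.0435). Of 15 visceral endoderm genes 11 fell (13 adjusted over the list alone, median -4.42, adjusted p = 1.99e-13, adjusted p = 0.0992 with an estimated correlation). Of 15 parietal endoderm genes 5 fell (6 adjusted over the list alone, median -0.32, adjusted p = 0.00873, adjusted p = 0.521 with an estimated correlation), led by Pth1r (-2.99 ± 0.26) and Lama1 (-3.59 ± 0.32). Of 16 naive pluripotency genes 3 fell (4 adjusted over the list alone, median -1.01, adjusted p = 5.19e-05, adjusted p = 0.451 with an estimated correlation), with Tdh at -5.56 ± 0.48. Of 12 general pluripotency genes 3 fell (5 adjusted over the list alone, median -0.94, adjusted p = 6.04e-04, adjusted p = 0.454 with an estimated correlation), with L1td1 at -1.92 ± 0.29. Of 13 hypoxia and glycolysis genes 6 fell (10 adjusted over the list alone, median -0.84, adjusted p = 6.11e-06, adjusted p = 0.451 with an estimated correlation), led by the mitophagy gene Bnip3 (-2.28 ± 0.34) and the glucose transporter gene Slc2a3 (-2.11 ± 0.34). Of 14 cholesterol synthesis genes 4 fell (6 adjusted over the list alone, median -0.35, adjusted p = 0.00130, adjusted p = 0.549 with an estimated correlation). Of 17 retinoic acid response genes edgeR called 0 over all genes tested, while 10 had an unadjusted p under 0.05, DESeq2 called 7 higher, and 7 rose adjusted over the list alone. The list was nevertheless called (median 0.74, adjusted p = 5.19e-05, adjusted p = 0.451 with an estimated correlation). Of 25 imprinted genes 9 rose and 1 fell (14 and 2 adjusted over the list alone, median 0.76, adjusted p = 3.91e-04, adjusted p = 0.451 with an estimated correlation). The primitive streak list (3 of 15 lower, 4 adjusted over the list alone), the p53 target list (1 of 15 higher, 1 adjusted over the list alone), the cell cycle list (1 of 16 lower, 3 lower and 1 higher adjusted over the list alone) and the 2-cell-like list (2 of 11 lower, 2 adjusted over the list alone) were also called, at adjusted p = 0.0455, 0.0183, 0.0455 and 0.0310. With an estimated correlation these were at adjusted p = 0.451, 0.454, 0.596 and 0.555. Without WT replicate 1 the calls of the parietal (median 0.02) and streak (-0.32) lists were lost, and without WT replicate 2 those of the p53 (0.30), cell cycle (-0.10) and 2-cell-like (-0.23) lists. Without KO replicate 1 the streak (-0.47), p53 (0.21) and cell cycle (-0.13) calls were lost, and without KO replicate 2 the parietal (-0.23), streak (-0.66) and 2-cell-like (-0.43) calls.

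**Figure D2:**
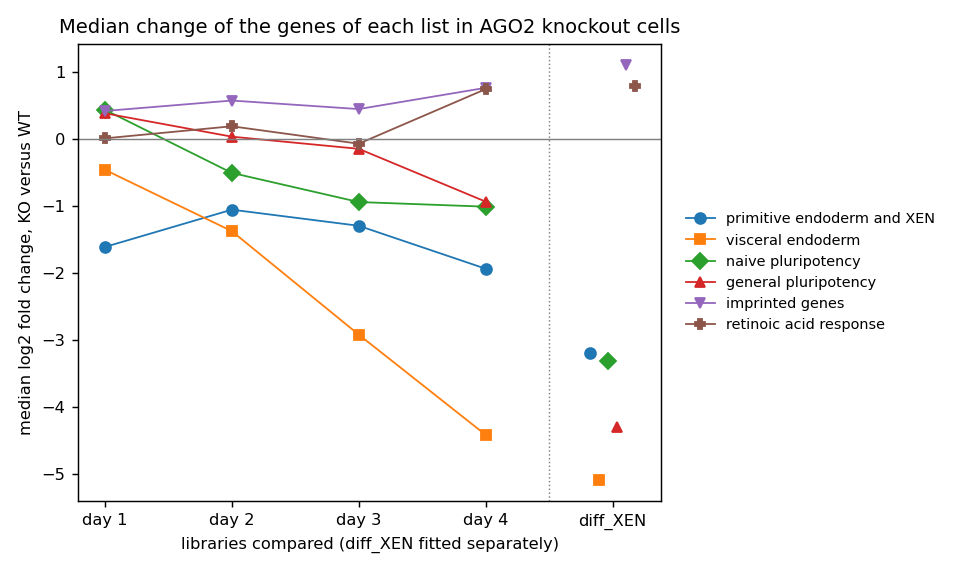
Median log2 fold change of KO versus WT over the members of 6 gene lists on each day and in diff_XEN, the last from a separate fit. The visceral endoderm median was -2.92 at day 3 and -4.42 at day 4, and the imprinted median lay above 0 in each comparison.

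The epiblast, epithelial, neuroectoderm, trophoblast, cardiac and vascular, and fibroblast lists were not called at day 4. Of 11 formative and primed epiblast genes 3 fell, led by the DNA methyltransferase gene Dnmt3b (-2.58 ± 0.20) and Otx2 (-5.45 ± 0.80), and adjusted over the list alone 4 fell and 2 rose (adjusted p = 0.197). Epithelial genes were split, with 1 of 12 higher and 4 lower (2 and 5 adjusted over the list alone, adjusted p = 0.230, called without WT replicate 2 at a median of -0.23), among them the claudin genes Cldn6 (-1.12 ± 0.16) and Cldn7 (-2.24 ± 0.34). Of 11 neuroectoderm genes only Pax6 was called (1.52 ± 0.27, 1 adjusted over the list alone, adjusted p = 0.197). Of 10 trophoblast genes only Plet1 was called (-1.80 ± 0.31, 1 adjusted over the list alone, adjusted p = 0.791). The trophoblast median was 0.37 and its mean -0.06. FGF and ERK response genes went both ways, 1 higher and 2 lower of 14 (3 and 3 adjusted over the list alone, adjusted p = 0.791), with Etv4 at -2.53 ± 0.28 and Spry4 at -2.28 ± 0.41, and a median of 0.05 beside a mean of -0.27. Activin and Nodal (1 of 9 lower, 3 adjusted over the list alone, adjusted p = 0.278), small RNA pathway (1 of 14 higher, 1 adjusted over the list alone, adjusted p = 0.151) and unfolded protein response (1 of 14 lower, 1 adjusted over the list alone, adjusted p = 0.376) lists were not called either. In the cardiac and vascular, fibroblast, interferon, mitochondrial and histone lists edgeR called 0 members, while 2, 7, 0, 0 and 2 had an unadjusted p under 0.05. DESeq2 called 2 fibroblast genes higher and 1 lower and 1 histone gene higher, and 0 in the cardiac, interferon and mitochondrial lists. Adjusted over the list alone, the fibroblast list had 3 higher and 2 lower, and the others had 0. Their camera adjusted p were 0.514, 0.125, 0.304, 0.873 and 0.943. Without WT replicate 1 the fibroblast (median 0.85) and interferon (1.01) lists were called. The mitochondrial and histone lists had medians of -0.08 and -0.07 and means of -0.03 and -0.01, with the test in the upward direction.

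Averaged over the 4 days, KO and WT differed in 3103 of 17694 genes, 1330 higher and 1773 lower in KO. Habp2 (-6.24 ± 0.30), Cubn (-5.45 ± 0.20), Aqp8 (-5.40 ± 0.41), Tfec (-5.33 ± 0.27), Tcf23 (-4.43 ± 0.25), Klb (-4.42 ± 0.17), Pga5 (-4.36 ± 0.28) and Amn (-3.85 ± 0.18) were among the lowest, of which Cubn and Amn belong to the visceral endoderm list, and Sox7 (-3.13 ± 0.15), Gata4 (-2.19 ± 0.12), Sox17 (-1.81 ± 0.23), Dab2 (-1.78 ± 0.11), Gata6 (-1.66 ± 0.21) and Pdgfra (-1.60 ± 0.18) were lower as well. Plagl1 (4.09 ± 0.34), H19 (3.76 ± 0.36), Nnat (2.49 ± 0.36), Fgf15 (2.04 ± 0.29), Msln (2.02 ± 0.13), Pax6 (1.95 ± 0.13) and Sema3e (1.65 ± 0.11) were among the highest. Of the primitive endoderm and XEN list 16 of 20 members fell (16 fell and 1 rose adjusted over the list alone, median -1.71, adjusted p = 1.23e-15, adjusted p = 0.0693 with an estimated correlation). Imprinted genes were higher in 13 of 25 cases and lower in 4 (15 and 4 adjusted over the list alone, median 0.60, adjusted p = 1.65e-04, adjusted p = 0.309 with an estimated correlation). On single days, 16 genes were called higher and 53 lower on all 4 days.

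In diff_XEN the endoderm genes Sox7, Sox17, Gata4, Pdgfra, Dab2 and Gata6 and the pluripotency genes Pou5f1, Esrrb and Nanog were lower in KO. Sox7 was at 132 ± 31.9 CPM in WT and 2.18 ± 1.05 CPM in KO (-5.82 ± 0.42, adjusted p = 0.00224), and Sox17 at 89.4 ± 7.20 and 3.02 ± 0.02 CPM (-4.85 ± 0.20, adjusted p = 0.00224). Gata4 (-3.24 ± 0.37), Pdgfra (-3.82 ± 0.56) and Dab2 (-2.88 ± 0.24) were lower, and Gata6 by -1.09 ± 0.34 (adjusted p = 0.0473). Pou5f1 stood at 89.3 ± 7.82 CPM in WT and 2.61 ± 2.33 CPM in KO (-4.95 ± 0.63, adjusted p = 0.00393), Esrrb was lower by -5.11 ± 0.31 and Nanog by -3.73 ± 0.97, and Sox2 did not differ past the threshold (-0.01 ± 0.66, adjusted p = 0.989). The apolipoprotein gene Apoa2 was at least 162-fold lower in KO. Count ratios of WT over KO were 1094 for Col6a5 (95% interval 196 to 43234), 362 for Slco4c1 (124 to 1759) and 287 for Mep1b (79.2 to 2374). Bglap3 (-8.53 ± 0.34), the ascorbate transporter gene Slc23a1 (-8.12 ± 0.59) and Enpep (-8.01 ± 1.15) fell too. Higher in KO were the cardiac actin gene Actc1 (6.91 ± 0.28), Stmn4 (6.81 ± 0.44), Grik4 (6.62 ± 0.67), Apol9a (6.57 ± 0.85), the immunoproteasome gene Psmb8 (6.29 ± 0.48), Wnt10b (6.01 ± 0.61) and Tmem179 (5.98 ± 0.58). In total 7835 of 16671 genes were called, 3685 higher and 4150 lower, against 5096 calls without WT library B, 4280 without clone C4 and 4180 without clone 5-3. The Nanog call was lost without clone C4 (-3.43) or clone 5-3 (-4.17), and that of Gata6 without WT library A (-1.37), WT library B (-0.77) or clone C4 (-0.70). The 2 KO libraries are different clones, so that each clone has 1 library.

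By list, 19 of 20 primitive endoderm and XEN genes fell in KO diff_XEN (19 fell and 1 rose adjusted over the list alone, median -3.20, adjusted p = 1.82e-06), including the endocytic receptor gene Lrp2 (-6.39 ± 0.32). Visceral endoderm genes fell in 12 of 15 cases (14 adjusted over the list alone, median -5.09, adjusted p = 9.38e-05), naive pluripotency genes in 12 of 14 (12 adjusted over the list alone, median -3.32, adjusted p = 1.17e-04) and cell cycle genes in 12 of 16 (12 adjusted over the list alone, median -1.25, adjusted p = 5.62e-04). With an estimated correlation they were at adjusted p = 0.519, 0.578, 0.519 and 0.519. Of 10 general pluripotency genes 6 fell (6 adjusted over the list alone, median -4.30, adjusted p = 0.0102, adjusted p = 0.519 with an estimated correlation), a call lost without WT library A (-3.35). All 12 interferon response genes rose (12 adjusted over the list alone, median 4.43, adjusted p = 6.98e-05, adjusted p = 0.578 with an estimated correlation), among them Ifitm3 (4.91 ± 0.55) and Irf9 (2.02 ± 0.23). Of 9 neuroectoderm genes 8 rose (8 adjusted over the list alone, median 2.28, adjusted p = 6.86e-04, adjusted p = 0.519 with an estimated correlation), with the intermediate filament gene Nes at 2.88 ± 0.29 and Tubb3 at 2.62 ± 0.27. Fibroblast and mesenchyme genes rose in 13 of 17 cases and fell in 2 (the same adjusted over the list alone, median 2.31, adjusted p = 0.00208, adjusted p = 0.578 with an estimated correlation), with N-cadherin, Cdh2, at 2.58 ± 0.21. The hypoxia and glycolysis list fell in 9 of 13 members (9 adjusted over the list alone, median -1.68, adjusted p = 9.88e-04, adjusted p = 0.519 with an estimated correlation), with Vegfa at -2.12 ± 0.17. Mitochondrially encoded transcripts fell in 6 of 13 cases (6 adjusted over the list alone, median -1.28, adjusted p = 0.00511, adjusted p = 0.695 with an estimated correlation). This list was included to stand for RNA quality or selection. A difference of that kind between these re-used KO and WT libraries cannot be told apart from genotype here.

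Calls at day 4 and in diff_XEN, which share no library, could be set against each other over 15385 genes tested in both. Of 340 genes higher in KO at day 4, 243 were also higher in KO diff_XEN, where independent lists of 340 and 3460 genes would share 76.5, and 4 were lower. Of 827 genes lower at day 4, 658 were also lower in diff_XEN, where 206 would be shared with its 3840 lower genes, and 3 were higher. Taken library by library, clone C4 was on the same side of the WT mean for 92.4% of the 340 and 95.3% of the 827 genes, and clone 5-3 for 87.1% and 93.7%. Among imprinted genes, H19 was at 3381 CPM in clone C4 and 13.4 CPM in clone 5-3, against 120 and 35.8 CPM in WT, and Plagl1 at 85.2 and 0.723 CPM against 0.974 and 0.875 CPM.

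**Figure D3:**
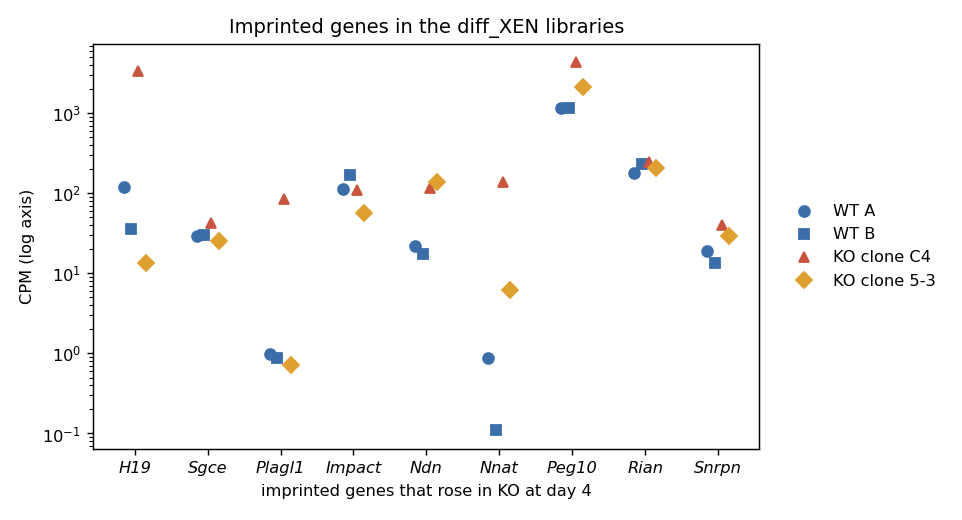
Levels in CPM on a log axis of the 9 imprinted genes that rose in KO at day 4, in each of the 4 diff_XEN libraries, with 1 symbol per library. H19, Plagl1 and Nnat lay at 3381, 85.2 and 139 CPM in clone C4 and at 13.4, 0.723 and 6.22 CPM in clone 5-3.

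WT diff_XEN cells differed from WT mESCs in 9415 of 17936 genes, 4880 higher and 4535 lower. Gata4 (6.05 ± 0.60), Gata6 (5.51 ± 0.57), Sox17 (5.84 ± 0.65), Sox7 (4.49 ± 0.61), Dab2 (5.68 ± 0.65) and Pdgfra (5.85 ± 0.70) rose, and Sox2 (-6.79 ± 0.74), Nanog (-5.22 ± 0.83), Esrrb (-4.44 ± 0.25) and Pou5f1 (-2.90 ± 0.54) fell. The fetal serum protein gene Afp was at least 720-fold higher, Svep1 at least 552-fold, Ugt1a7c at least 542-fold, Adam12 at least 463-fold and Pcdh7 at least 397-fold. Col3a1, Tnc and Ttr, which encodes transthyretin, were higher with count ratios of 20072 (95% interval 3602 to 792836), 6970 (2385 to 33803) and 3320 (919 to 27421). The largest falls were those of Fgf4 (-8.67 ± 0.56), Khdc3 (-8.42 ± 0.82), Nphs1 (-8.41 ± 0.50), Tdgf1 (-8.29 ± 0.53), Pipox (-7.71 ± 0.54), Lrrc34 (-7.67 ± 0.58) and Rasgrp2 (-7.37 ± 0.51), and Tdgf1-ps1, a near-identical copy of Tdgf1, is uncertain. All 20 primitive endoderm and XEN genes rose (20 adjusted over the list alone, median 5.84, adjusted p = 2.02e-09, adjusted p = 0.388 with an estimated correlation). So did 13 of 17 retinoic acid response genes (14 adjusted over the list alone), among them Rarb (8.90 ± 0.44) and Dhrs3 (7.06 ± 0.34). That list had a median of 5.68 and adjusted p = 4.26e-06, and adjusted p = 0.238 with an estimated correlation. Naive pluripotency genes fell in 14 of 16 cases (14 adjusted over the list alone, median -4.38, adjusted p = 4.12e-06, adjusted p = 0.339 with an estimated correlation). Interferon response genes rose in 10 of 12 cases (10 rose and 1 fell adjusted over the list alone, median 5.76, adjusted p = 9.12e-04, adjusted p = 0.657 with an estimated correlation). The passages of the mESC libraries differ, and both endpoints came from earlier studies. The WT course, sequenced in the same run and sharing no library with the endpoints, could be set beside this comparison over 16274 genes tested in both. Of 4504 genes higher at day 4 than at day 1, 3099 were also higher in diff_XEN than in mESC, where independent lists would share 1227, and 67 were lower. Of 3494 genes lower at day 4, 2358 were also lower in diff_XEN, where 906 would be shared, and 60 were higher. For the size of each change, and for genes that did not also move within the course, a batch and the cell state cannot be told apart here.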

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

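No test in this part was chosen after its result was seen. Every group holds 2 libraries, too few for a search for single libraries far from the rest. What follows stood out because the change from day 1 to day 4 differed between KO and WT in a direct test of that difference (edgeR, adjusted over all genes), given as the log2 change in KO minus that in WT.

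The change was lower in KO for Gjb1 (-7.48), Tdh (-6.83), the transporter and scaffold genes Slc23a1 (-6.75) and Pdzk1 (-5.74), Hnf4a (-5.31), Serpinb6c (-5.28), Otx2 (-4.87), Nrg2 (-4.68) and Gata4 (-1.55). The change was higher in KO for the chondrogenic regulator Sox9 (3.54), Tgfbr2 (2.87), Ulbp1 (2.51), Psd3 (2.36), Irs2 (2.28), Scube1 (2.24), Vash1 (2.23) and Lhfp (2.18). Gjb1, Tdh, Slc23a1, Pdzk1, Hnf4a, Serpinb6c and Nrg2 kept their call with each library left out in turn. Of the 8 genes with a higher change, each lost its call without KO day 1 replicate 2, where Sox9 was at 4.18, Tgfbr2 at 2.83, Ulbp1 at 2.04, Psd3 at 2.11, Irs2 at 1.91, Scube1 at 2.06, Vash1 at 1.91 and Lhfp at 2.19. Without WT day 1 replicate 2, Ulbp1 (2.22), Psd3 (1.81), Irs2 (1.86), Scube1 (2.18), Vash1 (1.97) and Lhfp (2.10) also lost it. Sox9 and Scube1 also lost it without WT day 1 replicate 1 (2.74 and 2.27), WT day 4 replicate 1 (3.56 and 2.26) or 2 (3.498 and 2.19) and KO day 4 replicate 1 (3.49 and 2.21) or 2 (3.56 and 2.25), and Sox9 without KO day 1 replicate 1 (3.003). Ulbp1 and Psd3 lost it without WT day 4 replicate 1 (2.496 and 2.41) or 2 (2.5 and 2.29) or KO day 4 replicate 2 (2.38 and 2.28). Lhfp lost it without WT day 1 replicate 1 (2.23), WT day 4 replicate 2 (1.78) or KO day 4 replicate 1 (1.66). The Otx2 call was lost without WT day 1 replicate 1 (-4.56) or 2 (-5.27), WT day 4 replicate 1 (-4.16), KO day 1 replicate 2 (-5.11) or KO day 4 replicate 1 (-4.65) or 2 (-5.18), and that of Gata4 without WT day 1 replicate 1 (-1.41) or WT day 4 replicate 1 (-1.44).

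Among lists the median difference was -2.88 for visceral endoderm, where 5 of 15 members had a lower change (7 adjusted over the list alone, camera adjusted p = 2.80e-06). It was -1.58 for the uncertain 2-cell-like copies, with 7 of 11 members lower (8 adjusted over the list alone, adjusted p = 2.80e-06). For naive pluripotency it was -1.61, with 4 of 16 members lower (6 adjusted over the list alone, adjusted p = 0.00182), and for general pluripotency -1.41, with 3 of 12 lower (9 adjusted over the list alone, adjusted p = 1.50e-04). With an estimated correlation these were at adjusted p = 0.635, 0.635, 0.662 and 0.653. Medians of -0.95 for hypoxia and glycolysis, -0.55 for primitive streak and mesendoderm and -0.47 for primitive endoderm and XEN came at adjusted p of 0.0182, 0.0214 and 0.0214. Medians of 0.83 for retinoic acid response, 0.72 for the small RNA pathway and 0.68 for reported targets of the miR-290 and miR-302 seed came at adjusted p of 0.00272, 0.00182 and 0.00775. None of these 6 lists was called with an estimated correlation, where the adjusted p was 0.662, 0.653, 0.662, 0.662, 0.653 and 0.653 in the order given. Members with a lower change numbered 1 of 13 for hypoxia (5 adjusted over the list alone), 3 of 15 for the streak list (5 adjusted over the list alone) and 5 of 20 for primitive endoderm (5 lower and 1 higher adjusted over the list alone). Members with a higher change numbered 2 of 17 for retinoic acid response (5 adjusted over the list alone), 1 of 14 for the small RNA pathway (7 adjusted over the list alone) and 2 of 10 for the microRNA targets (6 adjusted over the list alone). For the small RNA pathway the KO versus WT median was -0.52 at day 1, where DESeq2 called 7 members lower, and 0.17 at day 4. Its difference thus came mostly from a lower KO level at day 1. For the 2-cell-like list the KO versus WT median was 1.45 at day 1 and -0.37 at day 4. That difference came mostly from a higher KO level at day 1. The naive and general pluripotency medians were 0.43 and 0.38 at day 1, and -1.01 and -0.94 at day 4. The hypoxia list lost its call without day 1 replicate 1 of WT (-0.79) or of KO (-0.81), the streak list without KO day 1 replicate 1 (-0.74), and the primitive endoderm list without WT day 4 replicate 1 (-0.46) or KO day 1 replicate 1 (-0.44).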

How the results depend on the processing

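The fits without day 3 and with the mESC libraries added were chosen after the data were seen. Leaving out 1 library at a time moved the counts of calls from 2406 to between 45 and 4225 for KO versus WT at day 1, from 288 to 49 to 105 at day 2, from 854 to 271 to 2643 at day 3, from 1246 to 443 to 835 at day 4, from 3103 to 2266 to 3893 for the average over days and from 1136 to 222 to 3133 for the difference of the change. The ranges were 4180 to 6952 for KO versus WT in diff_XEN, 6081 to 7274 for day 4 versus day 1 in WT, 10025 to 11208 in KO and 6389 to 9043 for WT diff_XEN versus mESC. With 1 library left out, higher genes made up 38.1% to 58.7% of the calls at day 1, 22.4% to 54.2% at day 2, 19.2% to 54.9% at day 3, 11.4% to 31.02% at day 4, 40.01% to 52.2% for the average, 12.3% to 43.6% for the difference of the change and 44.5% to 52.5% in diff_XEN. With an additional 2-fold threshold, which by construction can only remove genes, the counts were 1050 at day 1, 776 at day 4, 767 for the average and 5260 for day 4 versus day 1 in WT. Without the expression filter they were 3754, 1094, 2035 and 2119 at days 1 to 4 and 2707 for the difference of the change. DESeq2 called 590 at day 2, 1327 at day 3 and 2208 for the difference, and its median over all genes in diff_XEN was -0.14. Only the 4 libraries of the day gave 1440 at day 2 and 35 at day 3. DESeq2 size factors in edgeR left all 10 counts within 1.5 times. Leaving out day 3 gave 3207 for the average. Apart from the 2-fold threshold and the smaller fits, the cause was not tested.

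Deviations of same-numbered libraries correlated at -0.18 to 0.39 over 28 pairs of groups, with 7 over 0.1, so the replicate numbers did not pair the samples throughout. The highest value, 0.39, was that between WT and KO at day 4, and of the 4 same-day pairs across genotype only 1 was over 0.1. Pairing on that day cannot be excluded, and no paired comparison of the day 4 libraries alone was made. A replicate block shared by all groups left all 8 counts of the course within 1.5 times, and a replicate block within genotype gave 877 at day 1, 180 at day 2 and 519 for the difference of the change. For the 2 endpoint comparisons no paired analysis was possible because their columns carry no replicate numbers.

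Among 280 list tests, 111 were no longer called with an estimated correlation and 45 with fry. In 1 case a called list changed direction, the unfolded protein and integrated stress response at day 3, with a median of 0.16 without WT day 3 replicate 2 and -0.77 without WT day 3 replicate 1, the ends of its range. For the 784 results on single genes, leaving out 1 library ended the call in 505 of 4371 refits, which concerned 167 results. A fit of only the 4 libraries ended it in 49 of 544, a replicate block within genotype in 47 and a shared one in 23 of 627, no filter in 7 and DESeq2 size factors in 2 of 784, DESeq2 in 3 of 776, leaving out day 3 in 4 of 77 and the added mESC libraries in 2 of 79, and none changed sign while called. Depth limited the genes near the floor of 3 counts, and in simulated counts few 2-fold changes were recovered in diff_XEN (10%). Only 200 genes were changed in that simulation, whereas 7835 were called in the real comparison. The adjusted p limit was therefore less strict in the real comparison, and the 10% does not carry over to it.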

Other observations

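In this part, the tests of a delayed course, leftover mESCs, a clone difference, a course running ahead and mixed WT cells were chosen after the results they bear on were seen. The list of genes reported as targets of let-7, a microRNA family that accumulates in differentiated cells, was called in the upward direction in KO versus WT at days 2, 3 and 4, with DESeq2 calling 2, 7 and 4 of its 13 members higher. By edgeR over all genes tested, 1 rose at day 1, where the list was not called (1 adjusted over the list alone, median -0.07, mean 0.02, adjusted p = 0.979). Members that rose numbered 2 at day 2 (6 adjusted over the list alone, median 0.47, camera adjusted p = 8.39e-06, adjusted p = 0.254 with an estimated correlation), 6 at day 3 (9 adjusted over the list alone, median 0.64, adjusted p = 4.24e-07, adjusted p = 0.163 with an estimated correlation) and 2 at day 4 (5 adjusted over the list alone, median 0.14, adjusted p = 0.0176, adjusted p = 0.451 with an estimated correlation). Ccnd1, the cyclin D1 gene, was higher by 1.58 ± 0.22 at day 3, and Lin28b, which encodes a let-7 binding protein, by 1.42 ± 0.22 at day 4. The day 4 call of the list was lost without WT replicate 2 (0.13) or KO replicate 2 (0.18). In diff_XEN the list was not called (median -0.008, adjusted p = 0.873), and 2 of 13 members were higher in KO and 4 lower, with the same counts adjusted over the list alone, among them Lin28b (2.84 ± 0.37) and Lin28a (-4.23 ± 0.50).

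Reported targets of the miR-290 and miR-302 seed, the microRNAs abundant in mESCs, were higher in 3 of 10 cases and lower in 1 at day 4 (5 and 1 adjusted over the list alone, median 0.49, adjusted p = 0.00610, adjusted p = 0.451 with an estimated correlation), a call lost without WT replicate 2 (0.44). The member that fell was Dkk1 (-1.90 ± 0.21). In diff_XEN 8 of 10 rose and 1 fell (the same adjusted over the list alone, median 1.06, adjusted p = 0.00758, adjusted p = 0.519 with an estimated correlation), with Lats2 at 1.89 ± 0.22 and Dkk1 again lower (-5.14 ± 0.55).

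The averaged count was set against other assignments of the same libraries. Among 60 assignments of the 4 libraries of each day to groups of 2, drawn from 648 possible, 1, the real assignment, gave as many as 3103 called genes, and the highest of the others gave 764. The other assignments mix KO and WT libraries in a group or swap them on some days. Either lowers the count for any steady difference between the cultures. The result therefore does not tell loss of AGO2 from another such difference.

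In diff_XEN 19 of 20 primitive endoderm and XEN, 12 of 14 naive and 6 of 10 general pluripotency genes were lower in KO, and each of the 3 list calls was lost with an estimated correlation (adjusted p = 0.519). A KO course that is delayed as a whole would keep pluripotency transcripts at or above WT. In diff_XEN the mean over the pluripotency lists differed between KO and WT by -3.19 ± 0.35 log2 CPM (95% interval -4.71 to -1.66), which argues against such a delay there. At day 4, where 3 of 16 naive and 3 of 12 general pluripotency genes were lower, the difference was -1.41 ± 0.53 (95% interval -3.71 to 0.88). That interval spans both signs, so the day 4 difference alone does not decide with 2 libraries per group. The limit had first been set at 2 standard errors, which the value exceeds, and was widened to the 95% interval after the value was seen. Both KO libraries of day 4 nevertheless had a lower list mean (2.79 and 3.74 log2 CPM) than every WT library of days 1 to 4 (4.43 to 6.60). A delay would place them within that WT range, so these levels argue against it for the pluripotency lists. Cells with the mESC profile left over in the WT diff_XEN cultures could carry Pou5f1, but the share of such cells that Sox2 allows would bring at most 17.9 CPM of Pou5f1, and the WT libraries held 94.8 and 83.7 CPM. Cells in another pluripotent state with little Sox2, and an effect of AGO2 loss on both gene groups, stay open and were not tested.

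Of 25 imprinted genes 9 rose and 1 fell in KO at day 4, and the call of the list was lost with an estimated correlation (adjusted p = 0.451). A KO course running ahead of WT as a whole might raise genes that increase with time, but it would raise the primitive endoderm and XEN list too, whose 20 measured members rose in WT from day 1 to day 4. The mean over that list was lower in KO at day 4 by a difference of -2.12 ± 0.12 log2 CPM (95% interval -2.62 to -1.63), which argues against a lead that includes this list. The list was already lower in KO at day 1 (median -1.62), so its level does not time the rest of the course. Other lists went the other way. From day 1 to day 4 the naive and general pluripotency medians fell to -3.79 and -3.90 in KO, against -1.90 and -1.70 in WT. A lead of other genes therefore stays open. The number already called higher at day 1, 5 of the 9, had been the first test of a lead and as a majority went against it, but not under a limit widened after the value was seen, so it decides nothing. A difference between knockout clones is a candidate explanation that stays open, since of the 9 genes 8 lay above both WT diff_XEN libraries in clone C4 and 4 in clone 5-3, but without H19, Plagl1 and Nnat, which had prompted the comparison, the numbers were 5 and 3 of 6, a difference of 2 under the limit of 3, from 1 library per clone. The clone of the day 1 to 4 KO libraries was not stated. H19 and Plagl1, higher in KO at day 4, lay above both WT diff_XEN libraries in clone C4 but not in clone 5-3. If the course came from 1 clone, a KO versus WT difference of its days could belong to that clone rather than to AGO2 loss. For the direction of most day 4 calls, the diff_XEN libraries argue against a cause private to 1 clone. Clone C4 differed from the WT mean in the day 4 direction for 92.4% of 340 higher and 95.3% of 827 lower genes. Clone 5-3 did so for 87.1% and 93.7%. These shares cover neither the size of a difference nor the calls of days 1 to 3. Loss of AGO2 acting on imprinted genes was not tested apart from the clone.

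KO libraries of day 4 kept 19.8% and 27.1% of the WT level of Ago2, and WT cells mixed into the KO cultures could be its source. Such cells would bring visceral endoderm transcripts in the same proportion. The visceral endoderm genes of at least 50 CPM in WT kept a median of 1.23% (Cubn 1.23%, Amn 1.16%, Apob 4.08%), which argues against mixing as the whole source, over only 3 genes. A transcript made from the edited gene stays open, as the counts do not show which part of Ago2 the reads cover.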
